A study of Mus musculus with 80 samples.

How the data were processed

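Gene expression was measured in the liver of male B6C3F1 mice, a hybrid laboratory strain, with Illumina bead arrays. The 80 arrays were placed in 19 groups from the titles in the labels, which give compound, dose and duration. Ethinyl estradiol (EE2) and prednisone (PRED) were mixed into the feed, and androstenedione (A4) was given by gavage in carboxymethyl cellulose, per the labels. The arrays sat on 10 chips of 8 arrays, and each chip held 6 to 8 groups. Each sample name holds a number, its meaning not given in the sources. 9 numbers were on several arrays, 19 in all, in every longer-duration group and some others, and 1 spanned 2 groups. The main fit ignored the number.

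Per the labels, RNA was extracted with Trizol and RNeasy columns and converted to biotinylated cRNA. The submitters' processing notes name GenomeStudio, with no version. The deposited table holds 1 normalized intensity per gene symbol and array on a linear scale. Beside each intensity, the authors deposited a detection p-value. It did not always follow the signal, since 535 entries, 22 of them not among the genes tested, had an intensity over 2 times the array median on an array that did not detect them, and 1.43% of undetected values lay that high. A gene not detected was therefore not always at background. The normalization is not given in the sources used here. The sorted intensities were nearly the same on every array, the pattern that quantile normalization leaves. No background appears to have been subtracted, because intensities ran from 85.91 to 19760.9 and the array medians from 105.7 to 106.4. A level near the median was therefore background, and signal over background limited what could be measured for weakly expressed genes. A second deposited value table, with 18132 entries, had equal intensities for the 18111 shared symbols and was used only to restore 21 symbols that a spreadsheet had turned into dates, through their identical values.

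Of the 18138 entries, 14307 carried a current symbol, 2702 an older symbol that was updated through the reference gene table, and 1129 a symbol not found there. An older symbol shared by several genes was left as it stood, a choice made after the first gene list output had been seen. 8 array control entries were left out. Genes with a detection p under 0.05 on at least 4 arrays were tested, which left 11352. The design had assumed several probes per gene, but the table has 1 entry per gene, so no choice among probes was needed.

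Intensities were analysed as log2(value + 16) with limma 3.58.1 in R 4.3.3. One linear model covered the 19 groups, with 61 residual degrees of freedom and a prior of 1.56, so all groups shared 1 estimate of each gene's spread. EE2 and PRED groups were compared with the feed control of the same duration, and A4 groups with the gavage control. Trends over the 4 doses at 7 d used scores from 0 for the control to 4 for the top dose. Differences between durations were tested as the 28 d change minus the 7 d change. EE2 was compared with PRED at the ppm values the compounds shared. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. All adjusted p-values for genes are limma's. Because of the added 16, a fold is on the log2(value + 16) scale and understates the change of low genes. Where a gene had a detection p of 0.05 or more on every array of a group, the change is given as at least N-fold. That value is the bright group's mean against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal detected on that array. In the dim group these genes had mean intensities of 93.8 to 107, at background. Where only some arrays of a group detected a gene, their number is given, and a fitted change against a level near background can understate the change.

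22 gene lists and 11 cell type lists were fixed before the data were examined, as were the comparisons, the tests, the filter, the alternatives and the rule for named genes, except where a later choice is stated. Of 517 list members, 467 were found in the table. 31 lists had at least 3 tested members. The adipocyte and pancreatic acinar lists had fewer and were not tested. Lists were tested at the top doses with limma's camera at a preset correlation of 0.01, which compares the members with all other genes. Members past the threshold were counted over all genes tested and, separately, adjusted over the list alone. Camera with an estimated correlation and fry, with statmod 1.5.0, were alternatives. Lists at lower doses and matched ppm have counts and medians only. Duration differences were tested the same way, both chosen after seeing the data.

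Named genes followed a rule. At the top dose and 7 d, the 8 largest rises and 8 largest falls were taken among genes past the threshold whose 4 treated arrays all lay above, or all below, every control. At 28 d, the 4 largest in each direction were taken. Predicted genes without a proper symbol were skipped, and 1 gene that the rule takes is not reported here. Up to 4 members of each list described, and Esr1 and Nr3c1, were added, and the 4 largest differences in each direction for matched ppm and durations. Genes named as shared between compounds, genes followed across doses, genes behind counts of 5 or fewer and genes shown for single low-dose arrays were chosen after their values were seen.

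Each test was run on simulated data with the real genes' levels and spreads and 200 of 11352 genes changed. For EE2 10 ppm at 7 d, 79.1% of log2 changes of 0.5 and 100% of 1 were found, with 4.12% of calls false. For A4 50 mg/kg/day at 7 d these were 76.1%, 97.0% and 5.21%. The PRED difference between durations found 52.2% and 83.6%. Of lists shifted by 1, 20 of 20 were found, and 6 of 600 others called. These rates do not cover members that vary together.

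Alternatives fixed in advance were the chip as a fixed or random block, the sample-name number as a random block, a fit of only the groups compared, pseudocounts 1 and 50, no filter, a filter of 20 arrays, each array centred on its median, a prior that follows the mean level, a fold of 1.5 besides the threshold, other trend scores, split controls and leaving out each array in turn. Chosen after seeing the data were a background correction with limma's nec, a run without feed control replicate 2 at 28 d and gavage control replicate 4 at 7 d, list counts and A4 and EE2 list shifts with each array left out in turn, and a run without arrays far from their own group. Of the first 2 arrays, the feed control stood apart for acute phase genes, and the gavage control was not far from its group (root mean square log2 distance 0.330, limit 0.409). Tables were read with version 1.17.8 of data.table and figures drawn with matplotlib 3.10.9 in python 3.11.15.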

Results

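The series compared, on 80 Illumina arrays of male mouse liver, ethinyl estradiol (EE2), a synthetic estrogen, prednisone (PRED), a glucocorticoid that the liver converts to its active form, and androstenedione (A4), a precursor of testosterone and estrone. EE2 was fed at 1, 2.5, 5 and 10 ppm and PRED at 1.25, 2.5, 5 and 25 ppm for 7 d, and A4 was gavaged at 2, 10, 20 or 50 mg/kg/day for 7 d. The top dose of each compound was also given for 28 d. Each treated group had 4 arrays, each gavage control 4 and each feed control 6. The number of arrays limits the precision, and since nothing in the labels says that arrays came from separate animals, p-values measure only the spread between these samples, which may be technical. Between 7743 and 9328 of 18138 entries were detected per array, at a detection p under 0.05.

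EE2 at 10 ppm for 7 d lowered 16 of 24 male-biased liver genes (list adjusted p = 0.00552 with an estimated correlation) and raised 10 of 11 macrophage markers (list adjusted p = 0.634 with an estimated correlation). Isyna1, which makes inositol phosphate from glucose, rose by 5.76 on the log2 scale (SE 0.55, adjusted p = 6.32e-13), from an intensity of 235 ± 169 (SD, n = 6) to 12409 ± 3973 (SD, n = 4). Hsd3b5, a male-specific steroid dehydrogenase, fell by 5.68 (SE 0.25, adjusted p = 3.61e-28), from 7390 ± 472 to 131 ± 31.8. Cyp8b1, the sterol hydroxylase that sets the cholic acid share of bile acids, fell by 5.18 (SE 0.37, adjusted p = 7.90e-18). Cyp17a1, a steroidogenic enzyme higher in female mouse liver, rose by 4.67 (SE 0.36, adjusted p = 3.48e-16).

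At 10 ppm and 7 d the sulfotransferase Chst8 also rose, by 4.82 (SE 0.43), the natriuretic peptide protease Corin by 4.25 (SE 0.19) and the stress cytokine Gdf15 by 4.13 (SE 0.28). Rgs7bp rose by 4.18 (SE 0.47) and the exonuclease Trex2 by 3.95 (SE 0.48). The keratin Krt79 was not detected in the controls and stood at least 25.8-fold higher with EE2 (adjusted p = 2.78e-12). The carbonic anhydrase Car3 fell by 5.25 (SE 0.55), Moxd1 fell by 3.44 (SE 0.62), the fatty acid hydroxylase Cyp4a12a fell by 3.33 (SE 0.35), the carboxylesterase Ces1f fell by 3.32 (SE 0.59) and Cyp2d40 fell by 3.26 (SE 0.23). Elovl3, a male-biased fatty acid elongase, was not detected with EE2 and stood at least 11.4-fold lower (adjusted p = 5.26e-14). Car3 was detected on 1 of the 4 EE2 arrays, and Chst8 and Trex2 on 5 and 3 of the 6 controls, at levels near background. The highest adjusted p among these genes was 1.30e-05, that of Moxd1.

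Of 24 male-biased liver genes, 16 fell and 0 rose (17 fell adjusted over the list alone), with a median log2 change of -1.06 (camera adjusted p = 4.47e-11). With chip as a block the median was -1.15 (adjusted p = 1.16e-11), and within the chips that held both groups it ran from -1.53 to -0.94. Of 15 female-biased genes, 3 rose and 0 fell, with no list shift (adjusted p = 0.266). They included Cyp17a1 and Cyp4a14, a fatty acid hydroxylase that stood at least 14.8-fold higher (adjusted p = 2.59e-05).

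Of 11 macrophage and Kupffer cell markers, 10 rose (11 adjusted over the list alone), with a median of 1.12 (adjusted p = 0.000601; adjusted p = 0.634 with an estimated correlation). The lysozyme gene Lyz2 rose by 1.77 (SE 0.49, adjusted p = 0.00306) and the complement receptor Vsig4 by 1.62 (SE 0.43, adjusted p = 0.00220). With chip as a block the median was 1.03 (adjusted p = 0.00364), and within chips it ran from 0.19 to 1.89. Among markers of other cell types, medians were 0.16 for endothelial cells, with 2 of 10 risen and 1 fallen, -0.09 for stellate cells, with 1 of 9 fallen, -0.07 for hepatocytes, with 0 of 10 past the threshold, and 0.20 for neutrophils, with 1 of 6 risen and 0 adjusted over the list alone. T and NK cell markers had a median of 0.00, with 1 of 10 fallen, and B cell and cholangiocyte markers each had 1 of 3 risen. None of these 7 lists shifted, the smallest adjusted p being 0.266. Endothelial markers had 5 risen, 0 fallen and a median of 0.29 (adjusted p = 0.152) without EE2 replicate 2, and 1 risen without replicate 3. Fallen stellate markers were 3 without feed control replicate 5, and each count of 1 in these lists moved without at least 1 array. Of 5 erythroid genes 2 fell, with a median of -0.44 (adjusted p = 0.0267; adjusted p = 0.503 with an estimated correlation; chip block -0.61, adjusted p = 0.0134; within chips -1.32 to -0.56). Alas2, the erythroid heme synthesis enzyme, fell by 2.68 (SE 0.22, adjusted p = 2.30e-15). The other, the hemoglobin gene Hba-a1, had a change of -1.37 (adjusted p = 0.0146), which was -0.62 (adjusted p = 0.292) without EE2 10 ppm replicate 2 and had an adjusted p of 0.121 with only the groups compared.

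Of 25 complement and coagulation genes, 12 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.53 (adjusted p = 0.000263; adjusted p = 0.443 with an estimated correlation). The clotting factor genes F7 and F10 fell by 1.14 (SE 0.18) and fell by 0.98 (SE 0.13). The chip-block median was -0.51 (adjusted p = 0.000130) and within-chip medians ran from -0.87 to -0.38. Of 15 fatty acid synthesis genes, 5 fell (5 adjusted over the list alone), with a median of -0.43 (adjusted p = 0.0267; adjusted p = 0.645 with an estimated correlation; chip block -0.48, adjusted p = 0.0215; within chips -0.55 to -0.09). The desaturase Fads2 fell by 1.78 (SE 0.25, adjusted p = 3.97e-08), and without EE2 10 ppm replicate 1 the 5 fallen genes were 3.

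Of 14 NRF2 targets, 5 rose (5 adjusted over the list alone), among them the transporter Abcc3, by 3.10 (SE 0.27), Pgd of the pentose phosphate pathway, by 1.63 (SE 0.28), and the sulfiredoxin Srxn1, by 1.20 (SE 0.27). The list median was 0.27 (adjusted p = 0.00681; adjusted p = 0.443 with an estimated correlation; chip block 0.27, adjusted p = 0.0129; within chips 0.11 to 0.61). Of 15 cell cycle genes, 6 rose (8 adjusted over the list alone), with a median of 0.23 (adjusted p = 0.00881; adjusted p = 0.645 with an estimated correlation; chip block 0.19, adjusted p = 0.0253; within chips 0.03 to 0.37). The replication licensing gene Mcm5 rose by 0.85 (SE 0.23). Of 8 estrogen receptor targets, 6 rose and 1 fell, the same numbers adjusted over the list alone, with a median of 0.26 (adjusted p = 0.0159; adjusted p = 0.411 with an estimated correlation; chip block 0.24, adjusted p = 0.0253; within chips 0.03 to 0.34). The cytokine receptor Lifr rose by 1.71 (SE 0.14), the chemokine Cxcl12, detected on 4 of 6 controls and 3 of 4 EE2 arrays but at mean intensities of 989 and 2524, by 1.32 (SE 0.16), and the scaffold gene Pdzk1 fell by 1.04 (SE 0.17), and without replicate 4 the 6 risen genes were 3. Of 21 glucocorticoid receptor targets, 8 rose (8 adjusted over the list alone), with a median of 0.47 (adjusted p = 0.0159; adjusted p = 0.503 with an estimated correlation; chip block 0.47, adjusted p = 0.0134; within chips 0.26 to 0.53). Ddit4 rose by 2.37 (SE 0.35), Sgk1 by 1.95 (SE 0.28) and Sds by 1.19 (SE 0.29).

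The other lists gave no shift with EE2 10 ppm at 7 d. Counts of risen and fallen members were 3 and 7 of 20 bile acid genes, 2 and 6 of 15 steroid-metabolizing enzymes, 3 and 6 of 22 gluconeogenesis genes, 6 and 0 of 16 ER stress genes, 2 and 7 of 19 cholesterol biosynthesis genes, 3 and 4 of 18 PPAR-alpha targets, 1 and 3 of 14 CAR and PXR targets, and 2 and 3 of 10 growth hormone-STAT5 genes. They were 4 and 0 of 20 acute phase genes, 0 and 2 of 14 interferon genes, 0 and 1 of 13 clock genes, 1 and 1 of 11 heat shock genes, 0 and 0 of 7 MHC class II genes, and 1 and 0 of 3 steroid receptors. The smallest adjusted p in this set was 0.118, for cholesterol biosynthesis. Risen ER stress genes were 1 without EE2 replicate 3 and 3 without feed control replicate 2, and fallen bile acid genes 4 without EE2 replicates 1 or 3. Risen acute phase genes were 2 without EE2 replicates 1, 3 or 4 or feed control replicate 4, and fallen PPAR-alpha targets 2 without EE2 replicates 2 or 3 or feed control replicate 2. Median, mean and test differed in sign for acute phase genes (-0.02, 0.01, upward), clock genes (median 0.05, downward), heat shock genes (median -0.01, upward), interferon genes (-0.02 and 0.00), cholangiocyte markers (-0.04 and 0.02) and T and NK markers (0.00036 and -0.01). In all, 2056 genes rose and 1727 fell with EE2 10 ppm at 7 d, of 11352 tested, 607 and 584 of them by at least 1.5-fold. In 18.8% of tested genes the 4 treated arrays did not overlap the 6 controls, against 0.952% by chance. With chip as a block 3481 genes passed. Of the called genes, 89.1% and 97.6% moved the same way within the 2 chips that held both groups.

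**Figure D1:**
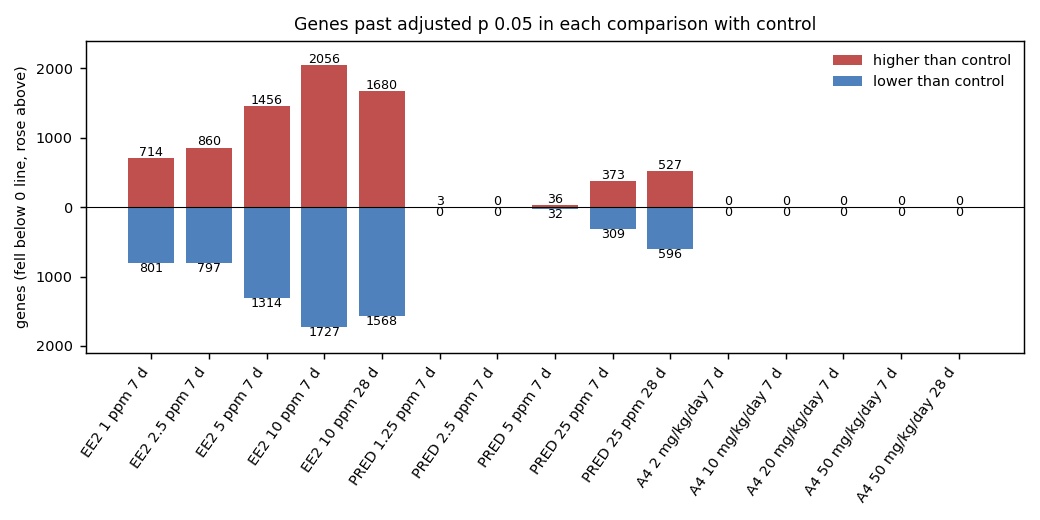
Bars give the number of genes past an adjusted p of 0.05 in each comparison with its control (x axis: compound, dose and duration; y axis: genes, risen above the 0 line and fallen below it). EE2 10 ppm had 2056 risen and 1727 fallen genes at 7 d, PRED 25 ppm 527 and 596 at 28 d, and A4 0 at every dose.

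Male-biased genes were already lower at 1 ppm of EE2. At that dose Hsd3b5 had fallen by 4.24 (SE 0.25), Cyp17a1 had risen by 4.50 (SE 0.36) and Gdf15 by 3.44 (SE 0.28). Male-biased genes that fell numbered 21, 21, 20 and 16 of 24 at 1, 2.5, 5 and 10 ppm, with medians of -1.20, -1.41, -1.34 and -1.06. Macrophage markers that rose numbered 1, 0, 2 and 10 of 11 at these doses, and female-biased genes 9, 10, 7 and 3 of 15. Risen glucocorticoid receptor targets were 10, 9, 8 and 8 of 21. Fkbp5, a sensitive glucocorticoid-induced gene, had changes of 1.60, 1.86, 1.38 and 0.97 (SE 0.30). Differences between doses were not tested by list. Isyna1 gained 1.24 per dose step (adjusted p for trend 3.43e-12). Car3, detected on 3, 2 and 1 of 4 arrays at 2.5, 5 and 10 ppm, fell by 1.19 per step (1.77e-11). The first step, control to 1 ppm, was 3.63 and -3.39, so a trend need not go beyond it.

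Risen and fallen genes numbered 714 and 801 at 1 ppm, 860 and 797 at 2.5 ppm, and 1456 and 1314 at 5 ppm. Without EE2 1 ppm replicate 1, the total at 1 ppm was 899 in place of 1515. With only the groups compared in the fit, the count was 641 at 1 ppm, 1160 at 5 ppm and 2529 for the trend. Non-overlapping genes made up 8.25%, 11.3% and 12% at these 3 doses. A trend, control included, was found in 3853 genes, 2128 rising and 1725 falling. Chip-block counts were 1352, 1921, 2591 and, for the trend, 3569. Within the chips that held both groups, 94.7% or more of called genes moved the same way at each of the 3 doses.

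After 28 d of EE2 10 ppm, 20 of 24 male-biased genes had fallen and 2 had risen, and 10 of 11 macrophage markers and 6 of 7 MHC class II genes had risen. With an estimated correlation these 3 lists had an adjusted p of 6.93e-05, 0.552 and 0.584. Isyna1 had risen by 6.39 (SE 0.55, adjusted p = 4.95e-15), and Prtn3, a neutrophil serine protease, by 5.91 (SE 0.56, adjusted p = 1.88e-13), from 129 ± 78.1 (SD, n = 6) to 8021 ± 584 (SD, n = 4). Prtn3 was near background in the controls, detected on 1 of 6. Chst8, detected on 4 of the 6, rose by 4.85 (SE 0.43), and Krt79 stood at least 42.3-fold higher (adjusted p = 9.45e-15). Hsd3b5 and Car3 were no longer detected and stood at least 58.8-fold (adjusted p = 7.05e-30) and at least 69.7-fold lower (adjusted p = 2.51e-14). Cyp4a12a fell by 5.07 (SE 0.35) and Cyp8b1 fell by 4.71 (SE 0.37).

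Of the 24 male-biased genes at 28 d, 20 fell and 2 rose (21 and 2 adjusted over the list alone), with a median of -1.57 (adjusted p = 6.51e-19; chip block -1.57, adjusted p = 3.69e-18; within chips -1.67 to -1.64). Of 15 female-biased genes, 5 rose and 1 fell, the same numbers adjusted over the list alone, with a median of 0.12 (adjusted p = 0.0298; adjusted p = 0.552 with an estimated correlation; chip block 0.10, adjusted p = 0.0390; within chips 0.04 to 0.22). Cyp17a1 rose by 4.45 (SE 0.36), Cyp2b9 by 2.61 (SE 0.57) and A1bg by 1.44 (SE 0.07), the last 2 from controls detected on 2 and 1 of 6 arrays. Estrogen receptor targets had 5 of 8 risen and 1 fallen (5 and 1 adjusted over the list alone), with a median of 0.57 (adjusted p = 7.19e-05; adjusted p = 0.0153 with an estimated correlation; chip block 0.58, adjusted p = 0.000318; within chips 0.48). The classical estrogen targets Ccn5 and Greb1, undetected in the controls, stood at least 5.98-fold (adjusted p = 6.67e-17) and at least 4.99-fold higher (adjusted p = 3.20e-30).

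Macrophage markers at 28 d had 10 of 11 risen, 10 also adjusted over the list alone, with a median of 1.38 (adjusted p = 4.65e-05; adjusted p = 0.552 with an estimated correlation; chip block 1.47, adjusted p = 4.03e-05; within chips 1.19 to 1.33). The complement component C1qc rose by 2.32 (SE 0.45) and Vsig4 by 2.14 (SE 0.43). Of 7 MHC class II genes 6 rose (6 adjusted over the list alone), with a median of 0.89 (adjusted p = 0.0173; adjusted p = 0.584 with an estimated correlation; chip block 0.96, adjusted p = 0.0193; within chips 0.84 to 1.05), among them the invariant chain Cd74, by 1.52 (SE 0.44), and 3 rose without EE2 10 ppm replicate 1. Medians of endothelial, stellate and T and NK cell markers were 0.05, -0.04 and 0.08. Of 20 acute phase genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.43 (adjusted p = 0.0173; adjusted p = 0.655 with an estimated correlation; chip block 0.48, adjusted p = 0.0218; within chips -0.05 to 0.52). The lipopolysaccharide-binding protein gene Lbp rose by 2.30 (SE 0.40). Feed control replicate 2 stood apart from the other controls for the acute phase mean, Lbp and Mt1, and was the only control behind the within-chip value of -0.05. Without it the median was 0.59 (adjusted p = 0.00218). These genes also stood higher in the 7-day than in the 28-day feed controls, by a median of 0.30. Glucocorticoid receptor targets had 9 of 21 risen (9 adjusted over the list alone), with a median of 0.39 (adjusted p = 0.0142; adjusted p = 0.552 with an estimated correlation; chip block 0.38, adjusted p = 0.0218; within chips 0.34 to 0.62), and the metallothionein Mt1 rose by 2.64 (SE 0.65).

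Fatty acid synthesis genes had 10 of 15 fallen at 28 d (12 adjusted over the list alone), with a median of -0.89 (adjusted p = 2.41e-05; adjusted p = 0.254 with an estimated correlation; chip block -0.83, adjusted p = 1.90e-05; within chips -1.02 to -0.29). Fads2 fell by 2.40 (SE 0.25) and the elongase Elovl6 fell by 1.70 (SE 0.37). Complement and coagulation genes had 10 of 25 fallen and 2 risen (11 and 2 adjusted over the list alone), with a median of -0.29 (adjusted p = 0.0115; adjusted p = 0.552 with an estimated correlation; chip block -0.38, adjusted p = 0.00876; within chips -0.40 to -0.33). C8b fell by 1.17 (SE 0.17) and F5 fell by 1.09 (SE 0.24). Of 5 erythroid genes 1 fell, Alas2, with a change of -3.73 (SE 0.22). The erythroid median was -0.27 (adjusted p = 0.0298; adjusted p = 0.552 with an estimated correlation), -0.61 with chip as a block (adjusted p = 0.0218) and -1.14 to -0.04 within chips. Without feed control replicate 2 at 28 d and gavage control replicate 4 at 7 d, its adjusted p was 0.0583. Among lists without a shift, NRF2 targets had 4 of 14 risen (adjusted p = 0.0545), interferon genes 4 of 14 risen (0.124), 2 without EE2 replicate 3, bile acid genes 3 risen and 7 fallen of 20 (0.171), and cholesterol genes 1 risen and 5 fallen of 19 (0.129; with chip as a block 0.0499). Median and mean differed in sign for CAR and PXR targets (0.09 and -0.11), growth hormone-STAT5 genes (-0.08 and 0.11) and heat shock genes (0.0089 and -0.17), with downward tests, and steroid receptors (0.0026 and -0.00095), none with a shift. In all, 1680 genes rose and 1568 fell at 28 d, 593 and 468 of them by at least 1.5-fold, 3250 in total with chip as a block. Non-overlapping genes made up 26%. Within chips, 97.1% and 99.2% of called genes moved the same way.

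The change with EE2 differed between durations for 290 genes, 154 more positive and 136 more negative at 28 d. Tspan8, a tetraspanin, went from a change of 1.10 at 7 d to 4.76 at 28 d, a difference of 3.66 (SE 0.35, adjusted p = 3.21e-12), with the gene detected on 1 of 6 controls at 7 d and 3 of 6 at 28 d. Cd63, a lysosomal tetraspanin, went from 0.20 to 2.43 (difference 2.23, SE 0.17, adjusted p = 1.28e-16), and the plasma peroxidase Gpx3 from 0.65 to 2.82 (difference 2.17, SE 0.22). Serpina1e, an alpha-1-antitrypsin gene, went from -0.16 to -3.89 (difference -3.73, SE 0.13, adjusted p = 5.13e-34). Only 0.141% of tested genes had a signal as high as its 15045 in the 7-day controls, a level at which saturation can hide a fall, and its paralog Serpina1a also fell at 28 d, by 1.17. Gstt3, a glutathione transferase, went from 1.14 to -1.69 (difference -2.83, SE 0.47, adjusted p = 4.40e-05).

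Most EE2 calls were shared by the durations. 1105 genes rose at both against 304 if the calls were independent, 905 fell at both against 239, and 11 moved in opposite directions. The changes correlated across genes with r = 0.81 and rho = 0.64, where genes are not independent replicates. The 290 differences became 254 with chip as a block and 110 with the sample-name number as a random block. Leaving out 1 array moved the count to 129 and 157 without EE2 10 ppm replicates 3 and 4 at 7 d, 192 without feed control replicate 2 at 7 d, 142 and 165 without feed control replicates 1 and 5 at 28 d, and 188 and 180 without EE2 10 ppm replicates 1 and 4 at 28 d.

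PRED at 25 ppm for 7 d raised 4 of 14 CAR and PXR targets, which serve drug metabolism, and 2 of 21 glucocorticoid receptor targets, and lowered 8 of 19 cholesterol biosynthesis genes. With an estimated correlation none of these 3 lists passed (adjusted p = 0.197, 0.197 and 0.177). Obp2a, a lipocalin, rose by 5.76 on the log2 scale (SE 0.38, adjusted p = 2.43e-19), from 223 ± 96.9 (SD, n = 6) to 12462 ± 2858 (SD, n = 4). Cyp2b10, the classical target of the xenobiotic receptor CAR, was not detected in the controls and stood at least 17.8-fold higher (adjusted p = 2.16e-41). Fkbp5 rose by 2.63 (SE 0.30, adjusted p = 1.40e-09). Ces1f, detected on 3 of the 4 PRED arrays, fell by 3.83 (SE 0.59, adjusted p = 3.91e-06). Serpina6, which encodes the plasma carrier of glucocorticoids, fell by 2.43 (SE 0.38, adjusted p = 6.86e-06).

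At 25 ppm and 7 d Wfdc12 also rose, by 4.06 (SE 0.55), Cyp17a1 by 3.74 (SE 0.36), the ketone body enzyme Oxct1 by 2.97 (SE 0.21) and Rnase2a by 2.87 (SE 0.41). Timp4, a metalloproteinase inhibitor, stood at least 10.9-fold higher (adjusted p = 4.84e-17), and Serpina5 at least 6.30-fold higher (adjusted p = 1.89e-14). The methyltransferase Inmt fell by 3.13 (SE 0.49), Car3 fell by 3.13 (SE 0.55), the thyroxine carrier Serpina7 fell by 2.26 (SE 0.38), Dnaic1 fell by 2.09 (SE 0.29) and Ces1e fell by 2.00 (SE 0.40). Serpina7 and Ces1e were detected on 2 and 3 of the 4 PRED arrays. Scd1, a stearoyl-CoA desaturase, fell by 2.54 (SE 0.68, adjusted p = 0.0122). Without PRED 25 ppm replicate 4 at 7 d its adjusted p was 0.143, and over all its alternatives it ran from 0.00547 to 0.143.

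Of 19 cholesterol biosynthesis genes, 8 fell and 0 rose (14 and 1 adjusted over the list alone), with a median of -0.87 (adjusted p = 1.22e-11; adjusted p = 0.177 with an estimated correlation; chip block -0.86, adjusted p = 2.91e-11; within chips -0.94 to -0.73). Pmvk fell by 1.19 (SE 0.21) and the lanosterol synthase Lss fell by 1.05 (SE 0.24). Of 15 fatty acid synthesis genes, 4 fell (4 adjusted over the list alone), with a median of -0.15 (adjusted p = 0.0199; adjusted p = 0.464 with an estimated correlation; chip block -0.12, adjusted p = 0.0333; within chips -0.81 to -0.13). Elovl5 fell by 1.21 (SE 0.21) and Fads2 fell by 1.12 (SE 0.25), and without replicate 4 the 4 fallen genes were 2. Of 14 CAR and PXR targets, 4 rose (5 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.000763; adjusted p = 0.197 with an estimated correlation; chip block 0.27, adjusted p = 0.000775; within chips 0.07 to 0.13). Besides Cyp2b10 they included Por, the electron donor of cytochromes P450, which was detected on 5 of 6 controls and rose by 1.49 (SE 0.30). The count of 4 was 2 without PRED 25 ppm replicate 2, 3 or 4, when the adjusted p was 0.0517, 0.0767 and 0.0722 for Cyp3a11 and 0.113, 0.0679 and 0.105 for Cyp3a13. With the sample-name number as a random block it was 0.0587 and 0.0777, and without feed control replicate 2 it was 0.0552 for Cyp3a11. Of 21 glucocorticoid receptor targets, 2 rose (2 adjusted over the list alone), with a median of 0.41 (adjusted p = 0.000763; adjusted p = 0.197 with an estimated correlation; chip block 0.45, adjusted p = 0.000426; within chips 0.03 to 0.91).

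Of 14 interferon genes 1 fell, Bst2, with a log2 change of -1.25 (SE 0.29). 7 fell adjusted over the list alone, with a median of -0.29 (adjusted p = 0.000999; adjusted p = 0.464 with an estimated correlation; chip block -0.32, adjusted p = 0.00115; within chips -0.53 to -0.08). Smaller list shifts, each with an adjusted p of 0.464 with an estimated correlation, were found for macrophage markers, with a median of -0.47 and 0 of 11 called (adjusted p = 0.0229), MHC class II genes, -0.52 and 0 of 7 (0.0240), PPAR-alpha targets, 0.33 and 1 of 18 risen, 3 adjusted over the list alone (0.0249), bile acid genes, 0.21 and 2 of 20 risen (0.0199), gluconeogenesis genes, 0.16 with 3 risen and 1 fallen of 22 (0.0415), and ER stress genes, 0.22 and 0 of 16 (0.0352; with chip as a block 0.0581). With chip as a block the first 5 medians were -0.47, -0.53, 0.39, 0.22 and 0.15, the highest adjusted p being 0.0238. Within chips they ran from -0.35 to -0.13, -0.40 to -0.34, -0.03 to 0.44, 0.07 to 0.19 and 0.01 to 0.24. T and NK cell markers had a median of -0.08 with 1 of 10 fallen (adjusted p = 0.0279; adjusted p = 0.414 with an estimated correlation; chip block -0.08; within chips -0.04). Acute phase genes had 1 of 20 risen (2 adjusted over the list alone) and a median of 0.10 (adjusted p = 0.123). Female-biased genes had 2 of 15 risen and 1 fallen, with a median of 0.02 (adjusted p = 0.0768) and 0.14 with chip as a block (adjusted p = 0.0379). In all, 373 genes rose and 309 fell, 124 and 119 of them by at least 1.5-fold, 723 in total with chip as a block. Non-overlapping genes made up 9.58%. Within chips, 96.9% and 98.7% of called genes moved the same way. The count was 412 without replicate 4, 422 without replicate 3, and 425 with the sample-name number as a random block.

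Below 25 ppm, PRED moved few genes. At 5 ppm Obp2a had risen by 3.11 (SE 0.38, adjusted p = 8.03e-08), Cyp17a1 by 3.15 (SE 0.36, adjusted p = 2.89e-08) and Fkbp5 by 1.39 (SE 0.30, adjusted p = 0.00841), and Ces1f had fallen by 2.85 (SE 0.59, adjusted p = 0.00565). Cyp2b10, not detected in the controls or at 1.25 and 2.5 ppm, was detected on 3 of 4 arrays at 5 ppm, at least 1.30-fold higher (adjusted p = 0.0544). At 1.25 ppm the 3 genes past the threshold were Cyp17a1, which rose by 2.08 (SE 0.36, adjusted p = 0.00336), Rnase2a, by 1.99 (SE 0.41, adjusted p = 0.0330), and the urea cycle enzyme Arg1, by 0.45 (SE 0.09, adjusted p = 0.0330).

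At 5 ppm 36 genes rose and 32 fell, 60 in total with chip as a block. Within chips 97.1% or more of them moved the same way, and non-overlapping genes made up 3.46%. The count was 32 without PRED 5 ppm replicate 1, 44 without feed control replicate 2 at 7 d, 43 without feed control replicate 6 at 7 d, 43 with only the groups compared and 45 with the sample-name number as a random block. At 2.5 ppm 0 genes passed in limma, where 396 had an unadjusted p under 0.05 and the smallest adjusted p was 0.449. 1 gene passed there without PRED 2.5 ppm replicate 1. At 1.25 ppm 499 genes had an unadjusted p under 0.05, and 1 gene passed without replicate 3, without replicate 4, or without feed control replicate 4 or 5 at 7 d. Non-overlapping genes at 1.25 and 2.5 ppm made up 1.29% and 0.661%, against 0.952% by chance. A trend over doses was found in 463 rising and 367 falling genes, 867 in total with chip as a block, 502 with the sample-name number as a random block and 510 without PRED 25 ppm replicate 4.

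After 28 d of PRED 25 ppm, 11 of 20 acute phase genes had risen, and 10 of 15 fatty acid synthesis and 6 of 19 cholesterol genes had fallen. With an estimated correlation these 3 lists had an adjusted p of 0.0686, 0.0389 and 0.358. Obp2a had risen by 6.30 (SE 0.38, adjusted p = 2.02e-21). Lcn2, an iron-carrier-binding lipocalin, had risen by 5.50 (SE 1.08, adjusted p = 0.000180), from 1201 ± 2402 (SD, n = 6) to 17447 ± 1314 (SD, n = 4), a level that only 0.0264% of tested genes reached and at which saturation can hide part of a rise. Hamp2, a hepcidin gene, fell by 4.61 (SE 0.68, adjusted p = 5.32e-07) and Inmt fell by 4.76 (SE 0.49, adjusted p = 1.59e-11). Wfdc12 rose by 5.18 (SE 0.55), and Timp4 stood at least 28.9-fold higher (adjusted p = 3.63e-24). Ces1f, detected on 1 of the 4 PRED arrays, fell by 5.13 (SE 0.59) and Car3 fell by 4.96 (SE 0.55).

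Of 20 acute phase genes, 11 rose (16 adjusted over the list alone), with a median of 0.47 and a mean of 1.44 (adjusted p = 1.33e-11; adjusted p = 0.0686 with an estimated correlation; chip block 0.45, adjusted p = 7.64e-10; within chips 0.50 to 0.94). The serum amyloid gene Saa3 rose by 4.32 (SE 1.02), the orosomucoid Orm2 by 3.58 (SE 0.90) and Saa1 by 3.31 (SE 0.74). The same 20 genes stood higher in 7-day than 28-day feed controls by a median of 0.30, 18 of 20 by sign and 1 past the threshold. 1 feed control at 28 d, replicate 2, had an Lcn2 intensity of 6100, where the other 5 lay between 136 and 383. Fatty acid synthesis genes had 10 of 15 fallen (12 adjusted over the list alone), with a median of -0.88 (adjusted p = 8.07e-11; chip block -0.91, adjusted p = 5.31e-11; within chips -1.02 to -0.57). Acly, which supplies cytosolic acetyl-CoA, fell by 1.72 (SE 0.32), Elovl5 fell by 1.65 (SE 0.21) and Elovl6 fell by 1.58 (SE 0.37). Cholesterol genes had 6 of 19 fallen (8 adjusted over the list alone), with a median of -0.44 (adjusted p = 9.93e-06; adjusted p = 0.358 with an estimated correlation; chip block -0.41, adjusted p = 2.20e-06; within chips -0.62 to -0.47), and Sc5d fell by 1.29 (SE 0.19).

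The growth hormone-STAT5 list had 5 of 10 fallen at 28 d, 5 also adjusted over the list alone, with a median of -0.42 (adjusted p = 0.00388; adjusted p = 0.0389 with an estimated correlation; chip block -0.38, adjusted p = 0.00605; within chips -0.76 to -0.21). The growth hormone receptor gene Ghr fell by 1.20 (SE 0.17), and the prolactin receptor gene Prlr, detected on 4 of 6 controls and no PRED array, stood at least 2.27-fold lower (adjusted p = 4.32e-07). The 5 fallen genes were 3 without any 1 of the 4 PRED arrays or feed control replicates 3, 5 or 6, and 2 without feed control replicate 1. Glucocorticoid receptor targets had 6 of 21 risen (6 risen and 3 fallen adjusted over the list alone), with a median of 0.37 (adjusted p = 0.000596; adjusted p = 0.172 with an estimated correlation; chip block 0.42, adjusted p = 0.000587; within chips 0.33 to 0.67). Mt1 rose by 3.87 (SE 0.65), to a level that only 0.0352% of tested genes reached and where saturation can hide part of a rise, Fkbp5 by 2.94 (SE 0.30) and the cell cycle inhibitor Cdkn1a by 1.75 (SE 0.27). NRF2 targets had 3 of 14 fallen (5 adjusted over the list alone), with a median of -0.15 (adjusted p = 0.00971; adjusted p = 0.410 with an estimated correlation; chip block -0.08, adjusted p = 0.0145; within chips -0.14 to -0.09). Abcc3 fell by 1.66 (SE 0.27), the epoxide hydrolase Ephx1 fell by 1.48 (SE 0.23) and Gstm1 fell by 1.16 (SE 0.22), and without feed control replicate 2 the 3 fallen genes were 5. Interferon genes had 0 of 14 called and a median of -0.27 (adjusted p = 0.00768; adjusted p = 0.847 with an estimated correlation; chip block -0.32, adjusted p = 0.00235; within chips -0.33 to -0.28). CAR and PXR targets had 5 of 14 risen and 1 fallen, with a median of -0.13, a mean of 0.19 and an upward test (adjusted p = 0.209), and 3 rose without PRED replicate 1. Cyp2b10 on that list stood at least 23-fold higher (adjusted p = 1.25e-43). Male-biased genes had 5 risen and 4 fallen of 24 (adjusted p = 0.988), 2 fallen without PRED replicate 1, and macrophage markers 0 of 11 called, with a median of -0.08 (adjusted p = 0.923). MHC class II genes and PPAR-alpha targets had medians of -0.34 and -0.26 (adjusted p = 0.0672 and 0.0858), and -0.40 and -0.28 with chip as a block (adjusted p = 0.0430 and 0.0367). Median and mean differed in sign for male-biased genes (-0.03 and 0.15), steroid-metabolizing enzymes (-0.18 and 0.11), endothelial markers (-0.06 and 0.10), cholangiocyte markers (0.05 and -0.05) and heat shock genes (0.0016 and -0.19), none with a shift. In all, 527 genes rose and 596 fell, 201 and 212 of them by at least 1.5-fold, 1017 in total with chip as a block and 685 with the sample-name number as a random block. Non-overlapping genes made up 13%. Within chips, 99.5% and 97.6% of called genes moved the same way.

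The PRED change differed between durations for 161 genes, 103 more positive and 58 more negative at 28 d. Trat1 had a fitted difference of 2.76 (SE 0.54, adjusted p = 0.00720), with the gene detected on 2 of 6 controls at 7 d and on none at 28 d, where it stood at least 9.62-fold higher with PRED (adjusted p = 7.81e-10). Cyp3a11, the major PXR-induced cytochrome P450, went from 1.44 to -1.08 (difference -2.52, SE 0.57, adjusted p = 0.0213), and Acsl1, which activates fatty acids, had a difference of -2.07 (SE 0.48, adjusted p = 0.0220). Without PRED 25 ppm replicate 1 at 28 d, or replicates 3 or 4 at 7 d, the adjusted p was 0.0722, 0.0700 and 0.0579 for Cyp3a11 and 0.0722, 0.0700 and 0.0721 for Acsl1. Over all alternatives it ran from 0.000126 to 0.0616 for Trat1, from 0.00412 to 0.130 for Cyp3a11 and from 0.00770 to 0.15 for Acsl1.

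145 genes rose with PRED at both durations against 17.3 if independent, 116 fell at both against 16.2, and 3 moved in opposite directions, with r = 0.50 and rho = 0.12 across genes. The count of 161 was 52 with chip as a block and 4 with the sample-name number as a random block. Without single PRED 25 ppm arrays at 7 d it was 483, 44, 20 and 8 for replicates 1 to 4, and at 28 d it was 22 and 47 for replicates 1 and 2 and 65.8% of the 161 for replicate 3. Without feed controls at 7 d it was 32, 77 and 248 for replicates 1, 2 and 4, and without those at 28 d it was 27, 392, 61, 451, 32 and 64 for replicates 1 to 6.

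**Figure D2:**
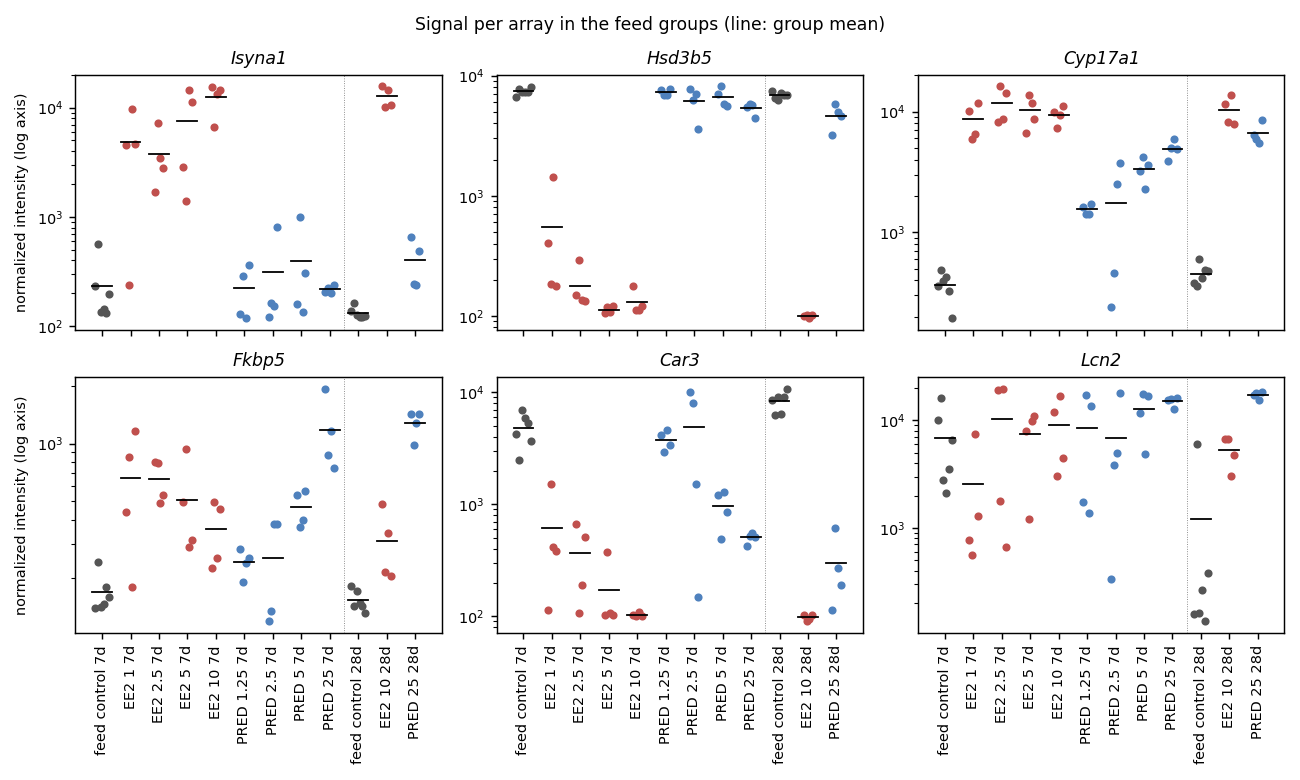
Points give the normalized intensity of 6 genes on each feed array (y axis, log scale) by group (x axis), and lines give group means. Hsd3b5 averaged 7390 in the 7-day feed controls and 131 with EE2 10 ppm, and Lcn2 spread between 2119 and 16266 in the 7-day feed controls.

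At matched feed concentrations EE2 and PRED were compared directly with 4 arrays each. At 2.5 ppm Hsd3b5 was lower with EE2 by a log2 difference of -5.01 (SE 0.27, adjusted p = 4.76e-23), and so were Cyp4a12a, by -3.83 (SE 0.39), Scd1, by -3.73 (SE 0.74), and Elovl3, detected on 1 of the 4 EE2 arrays, by -3.46 (SE 0.35). Cyp4a14, detected on 2 of the 4 PRED arrays, was higher with EE2 by 5.31 (SE 0.81), Prtn3 by 3.83 (SE 0.61), Isyna1 by 3.77 (SE 0.60) and Gdf15 by 3.66 (SE 0.30). At 5 ppm Hsd3b5 differed by -5.68 (SE 0.27), Moxd1 by -4.70 (SE 0.68), Rnase2a, detected on 2 of the 4 EE2 arrays, by -4.54 (SE 0.45) and Cyp8b1 by -4.14 (SE 0.40). Isyna1 was higher with EE2 by 4.07 (SE 0.60), Gdf15 by 3.90 (SE 0.30) and Mmd2 by 3.76 (SE 0.33), and Krt79 stood at least 13.1-fold higher (adjusted p = 9.80e-08). Male-biased genes were lower with EE2 for 20 of 24 members at 2.5 ppm and 20 at 5 ppm, with medians of -1.35 and -1.44.

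In all, 656 genes were higher and 462 lower with EE2 than with PRED at 2.5 ppm, and 1091 and 957 at 5 ppm. Chip-block totals were 1111 and 1978. Totals with only the groups compared, a fit that takes the spread from those groups alone, were 443 and 231. There the adjusted p at 5 ppm was 0.0765 for Isyna1, 0.0581 for Krt79 and 0.0631 for Cyp8b1, and at 2.5 ppm it was 0.102 for Scd1. Each was the highest of its alternatives, the lowest being 3.25e-08, 7.82e-09, 1.30e-18 and 1.72e-05. For 94.2% of genes at 2.5 ppm and 92.1% at 5 ppm, the 95% confidence interval lay within 2-fold, with changes near background understated.

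EE2 10 ppm and PRED 25 ppm, which differ in dose, were set side by side. At 7 d Cyp17a1 rose with both, by 4.67 and 3.74. Mmd2 and Gas6 rose with EE2, by 3.35 and 3.27, and had changes of -1.44 and -1.22 with PRED. Rnase2a had changes of -1.93 with EE2, where 3 of 4 arrays detected it, and 2.87 with PRED. At 28 d Lcn2 rose by 3.72 and 5.50, the second where saturation can hide part of a rise, Cxcl14, detected on 5 of 6 controls, by 3.52 and 3.08 and Wfdc12 by 2.75 and 5.18, and Ces1e had a change of -3.10 with EE2 and, not detected with PRED, stood at least 10.3-fold lower there (adjusted p = 1.33e-09).

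At 7 d 301 genes changed the same way, 111 up and 190 down, against 67.6 and 47 if the calls were independent. 47 genes changed in opposite directions. Both comparisons shared controls. Simulations of unchanged groups (50, highest count 0) do not test this, since these give few calls. With controls split 3 and 3, the median count of 20 splits was 123 (100 to 176), and its value if independent was not computed. The covariance of changes was 0.0296 (simulated 0.00576). At 28 d 479 genes changed the same way, 156 up and 323 down, against 78 and 82.3, and 67 in opposite directions. The simulated highest was 1, the split-control median 249.5, from 186 to 344, and the covariance 0.0539 against 0.00725. Chip-block counts were 290 and 409. The count at 7 d was 182 without PRED 25 ppm replicate 4, 187 without replicate 3 and 181 with the sample-name number as a random block, and at 28 d it was 279 with that block. Correlations across genes were 0.24 and 0.33, below the simulated 0.35 and 0.38.

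**Figure D3:**
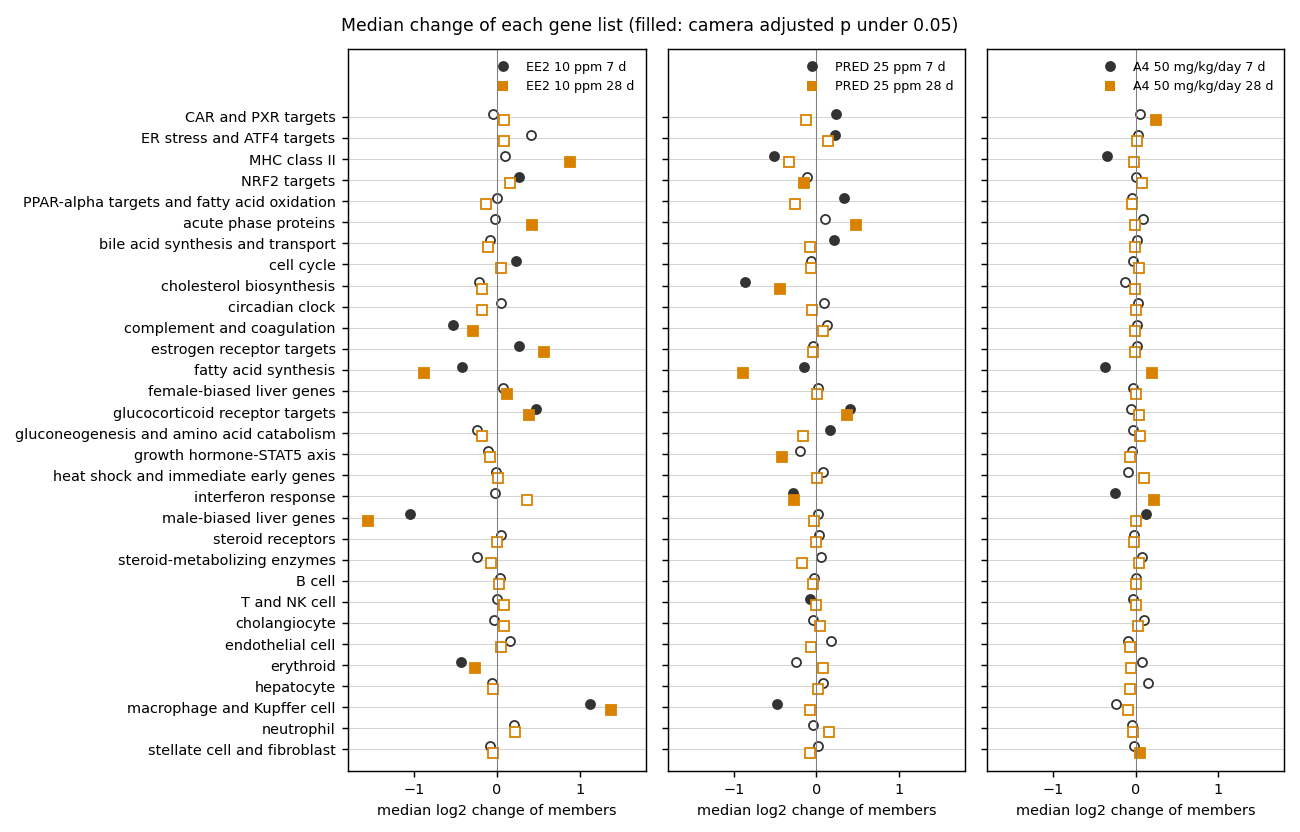
Points give the median log2 change of each gene list (y axis: list; x axis: median log2 change) for EE2, PRED and A4 at the top dose, with circles for 7 d, squares for 28 d and filled symbols for lists with a camera adjusted p under 0.05. Male-biased genes lay at -1.06 and -1.57 with EE2, macrophage markers at 1.12 and 1.38 with EE2, and acute phase genes at 0.47 with PRED at 28 d.

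A4 moved no single gene past the threshold at any dose. Fatty acid synthesis genes had a median change of -0.37 at 50 mg/kg/day and 7 d with 0 of 15 called (adjusted p = 2.85e-05; adjusted p = 0.479 with an estimated correlation; chip block -0.40, adjusted p = 3.01e-05; within 1 chip -0.32). At 28 d the same list had a median of 0.19 (adjusted p = 0.0138; adjusted p = 0.695 with an estimated correlation; chip block 0.39, adjusted p = 0.00219). At 7 d the interferon median was -0.25 (adjusted p = 0.000103), the MHC class II median -0.34 (adjusted p = 0.000390) and the male-biased median 0.12 (adjusted p = 0.000818), each with an adjusted p of 0.479 with an estimated correlation. With chip as a block they were -0.19 (0.0102), -0.28 (0.0301) and 0.08 (0.0301), and within the 1 chip that held both groups 0.02, 0.00 and 0.03. With each of the 8 arrays left out in turn, the interferon median lay between -0.41 and -0.25 and the MHC class II median between -0.51 and -0.22, except without gavage control replicate 4, when they were 0.06 (adjusted p = 0.264) and 0.10 (adjusted p = 0.737). The male-biased adjusted p was 0.0981 and 0.0750 without gavage control replicates 3 and 4. Without that array and feed control replicate 2 at 28 d, acute phase genes (0.23, adjusted p = 0.000220) and endothelial markers (-0.16, adjusted p = 0.0243) passed too, each with an adjusted p of 0.676 with an estimated correlation. At 28 d CAR and PXR targets had a median of 0.24 with 0 of 14 called, 2 adjusted over the list alone (adjusted p = 0.000703; adjusted p = 0.124 with an estimated correlation; chip block 0.09, adjusted p = 0.0484), stellate cell markers 0.05 (adjusted p = 0.00685; adjusted p = 0.124 with an estimated correlation; chip block 0.06, adjusted p = 0.0744) and interferon genes 0.23 (adjusted p = 0.00270; adjusted p = 0.695 with an estimated correlation; chip block 0.20, adjusted p = 0.0746). No chip held both A4 and gavage control arrays at 28 d. Cholesterol genes at 7 d and cell cycle genes at 28 d had medians of -0.12 and 0.04 (adjusted p = 0.154 and 0.0826), and -0.28 and 0.07 with chip as a block (adjusted p = 0.0109 and 0.0269). Median, mean and test differed in sign for 3 other A4 lists at 7 d, with medians from -0.03 to 0.03, and for 9 at 28 d, with medians from -0.07 to 0.0013, none with a shift.

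With limma 0 genes passed at any of the 4 A4 doses for 7 d or at 50 mg/kg/day for 28 d, where, in order of dose and duration, 596, 225, 303, 429 and 261 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.179. 1 gene passed at 2 mg/kg/day without gavage control replicate 3 at 7 d. No dose trend passed (319 genes had an unadjusted p under 0.05, smallest adjusted p 0.823). Non-overlapping genes made up 2.77%, 1.26%, 1.79%, 2.63% and 2.75%, against 2.86% by chance for 4 arrays against 4. For 97.2% or more of genes at each dose, the 95% confidence interval lay within 2-fold, with changes near background understated. The single gene that differed between durations was Serpina9, with a change of 0.27 at 7 d and -0.22 at 28 d (difference -0.49, SE 0.09, adjusted p = 0.0296). It did not pass with chip as a block, nor without A4 replicates 1, 2 or 4 at 7 d or 1 or 3 at 28 d, or gavage control replicates 1, 3 or 4 at 7 d or 2 or 3 at 28 d. Its adjusted p ran from 0.00483 to 0.979 over its alternatives.

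Between gavage and feed controls limma called 0 genes at 7 d, with 1333 at an unadjusted p under 0.05 and a smallest adjusted p of 0.226, and at 28 d 0, with 435 and 0.563. With only the control groups in the fit, 4 genes passed at 7 d. Without feed control replicate 2 at 28 d 2 genes passed, and without replicate 4 1 gene. The estrogen receptor gene Esr1 was not among the genes tested. The glucocorticoid receptor gene Nr3c1 had changes of 0.04 with EE2 at 7 d and 0.03 with PRED, near background.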

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

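The tests of explanations for the acute phase, macrophage and Serpina1e patterns were chosen after those results were seen, except the one on genes of the macrophage markers' signal level, and so were the list tests of durations. The counts over other splits of the arrays had been chosen beforehand.

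Acute phase genes differed in their PRED change between durations, by a median log2 difference of 0.42 (adjusted p = 4.92e-06; adjusted p = 0.498 with an estimated correlation). A single wrong control is argued against by a difference of at least 0.37 with each of 12 feed controls left out. So is a swap of a 7-day with a 28-day control. On a scale from 0, the 28-day control mean, to 1, the 7-day mean, every 7-day control lay at 0.632 or higher. 28-day replicate 2 itself lay at 1.11. Chips are argued against only for the 28 d change, with a chip-block median 0.940 times that without, and stay open for the difference. 7-day feed controls stood above 28-day ones by a median of 0.30 (quartiles 0.10 and 1.34, 1 of 20 genes called, list adjusted p = 6.09e-08). PRED arrays at 28 d stood above those at 7 d by 0.11. A candidate explanation is therefore a control difference of unknown origin, and a biological effect of longer treatment, not tested apart from it, stays open.

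Macrophage markers rose with EE2 10 ppm at both durations, Vsig4 at 28 d from 1092 ± 283 (SD, n = 6) to 4772 ± 486 (SD, n = 4). A lower share of hepatocytes would raise markers of other cell types alike, but the highest median among endothelial, stellate and T and NK cell markers at 28 d was 0.081, and at most 0.109 with any 1 array left out, where the macrophage median was 1.38. Chips are argued against by a chip-block median at least 0.918 times that without. Whether all genes at that signal level rose is left open, since near-equal arrays largely fix their median (-0.030 over 6500 genes). More macrophages, or more of these transcripts in each, may account for the rise, a hypothesis the data do not resolve. Loss of the list call with an estimated correlation (adjusted p = 0.552 at 28 d) leaves open that members vary together between arrays.

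Serpina1e fell with EE2 10 ppm at 28 d, from 14858 ± 933 (SD, n = 6) to 990 ± 98.7 (SD, n = 4), while at 7 d it had 15045 ± 1049 and 13559 ± 2188. Signal shared with other Serpina1 genes cannot be told apart from a fall of this gene alone, because Serpina1b and Serpina1d, with changes of -0.04 and -0.16 at 28 d, lay in the top 0.0881% of genes, where a fall can stay hidden, and Serpina1a fell by 1.17 (adjusted p = 3.33e-05), from 4042 to 1760. Chips are argued against by a smallest change of -3.70 within the 2 chips that held both groups. Saturation at 7 d cannot be told apart from an unaltered level, because only 0.141% of genes tested lay at or above the Serpina1e control signal. A late fall of this transcript could be an effect of longer treatment, which stays a hypothesis.

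The EE2 change differed between durations by 3.66 for Tspan8, 2.75 for Cxcl14, 2.23 for Cd63, 2.17 for Gpx3, -3.73 for Serpina1e, -2.83 for Gstt3, -1.99 for Retsat and -1.74 for Cyp4a12a, in log2 at 28 d minus 7 d. Of these, Cxcl14, Retsat and Cyp4a12a had adjusted p-values of 0.0425, 0.0479 and 0.0429. Leaving out 1 array ended their calls for 14, 17 and 13 of the 20 arrays, and over all alternatives the adjusted p ran from 0.0147 to 0.134, from 0.00126 to 0.129 and from 0.0113 to 0.162. The PRED change differed by 3.34 for Crybb3, 3.29 for Saa2, 2.76 for Trat1, 2.07 for Dnajc12, -2.52 for Cyp3a11, -2.35 for Slc17a8, -2.07 for Acsl1 and -1.41 for Abcc3. Leaving out 1 array ended the calls of Crybb3, Saa2, Dnajc12, Slc17a8 and Abcc3 for 13, 12, 15, 14 and 13 of 20 arrays. Over all alternatives their highest adjusted p was 0.196, 0.190, 0.225, 0.207 and 0.230, and their lowest 0.0162, 0.00569, 0.0247, 0.0179 and 0.0184. The A4 change of Serpina9 differed by -0.49, with the gene detected on 2 of 4 gavage controls at 7 d and 2 of 4 A4 arrays at 28 d. Dnajc12 had mean intensities of 259 and 506 with PRED and 528 and 192 in the controls at 7 d and 28 d, above background, although only 1 of these 20 arrays detected it.

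Lists that differed between durations with EE2 had median differences of 0.34 for acute phase genes (adjusted p = 0.0171), 0.0015 for estrogen receptor targets (0.0364), -0.43 for fatty acid synthesis (0.0244), 0.28 for interferon genes (0.0364), -0.42 for male-biased genes (0.00167), 0.53 for MHC class II genes (0.0244) and 0.066 for T and NK cell markers (0.0364). For the acute phase genes the same feed controls as for PRED stood 0.30 higher at 7 d than at 28 d, and the EE2 arrays at 28 d differed from those at 7 d by a median of -0.056. With PRED the list differences were -0.41 for bile acid genes (0.00258), -0.49 for fatty acid synthesis (0.000436), -0.40 for gluconeogenesis (0.00107), -0.80 for PPAR-alpha targets (0.000436) and -0.12 for stellate cell markers (0.0241), besides acute phase genes. With A4 they were 0.087 for cell cycle genes (0.0185), 0.55 for fatty acid synthesis (8.75e-07), 0.35 for heat shock genes (0.0140), -0.12 for hepatocyte markers (0.0140), 0.44 for interferon genes (8.70e-07), -0.11 for male-biased genes (0.0150) and 0.37 for MHC class II genes (0.0104). None of these passed with an estimated correlation (smallest adjusted p = 0.331). Without gavage control replicate 4 at 7 d and feed control replicate 2 at 28 d, the A4 differences were 0.085 for interferon genes (adjusted p = 0.331), -0.12 for MHC class II genes (0.934), 0.024 for cell cycle genes (0.465), 0.17 for heat shock genes (0.181), -0.12 for hepatocyte markers (0.0536) and -0.050 for male-biased genes (0.152), so of the 7 A4 lists only fatty acid synthesis passed, at 0.62 (3.68e-09; adjusted p = 0.0607 with an estimated correlation). In that run acute phase, gluconeogenesis and stellate cell lists also passed for A4 (smallest adjusted p = 0.281 with an estimated correlation), and the EE2 and PRED lists kept their calls.

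In 28 cases 1 array stood apart from its group, in log2 signal. Chance gives about 1 in 20 groups, and 26 of 279 groups of named genes, 2 of 30 of lists and 0 of 19 of detected genes stood apart, against 13.95, 1.5 and 0.95 by chance. Feed control replicate 2 at 28 d was the highest of its group for the acute phase mean, at 11.95 against 10.59 to 10.84, and for Lcn2 at 12.58, Saa1 at 11.30, Saa3 at 9.95, Lbp at 11.04, Mt1 at 13.21 and Prtn3 at 8.25, and stood apart for Elovl6 at 9.44, Inmt at 11.55 and Acly at 12.14. Feed control replicate 6 at 28 d stood apart for Cyp2b9 at 7.46. Feed control replicate 2 at 7 d stood apart for Isyna1 at 9.20, Gdf15 at 7.19, F10 at 13.12, Por at 8.62 and Cyp3a11 at 8.54, and replicate 6 for Cxcl12 at 9.77. EE2 10 ppm replicate 1 at 7 d stood apart for Hsd3b5 at 7.60, and replicate 2 for Srxn1 at 10.25 and C9 at 7.63, where the others lay between 11.32 and 11.83. C9 had a change of -1.83 with EE2 (adjusted p = 0.00331), which without that array had an adjusted p of 0.162, in a range over its alternatives of 0.00117 to 0.162. EE2 10 ppm replicate 1 at 28 d stood apart for Mt1 at 13.02, PRED 25 ppm replicate 3 at 7 d for Lcn2 at 13.63 and at 28 d for Hamp2 at 7.56. A4 50 mg/kg/day replicate 4 at 7 d had a macrophage mean of 8.64 against 8.16 to 8.23. At lower doses these were PRED 2.5 ppm replicate 4 for Prtn3 at 10.43 and Isyna1 at 9.69, EE2 2.5 ppm replicate 2 for Hsd3b5 at 8.27 and replicate 1 for Elovl3 at 7.10.

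Other splits of the same arrays were counted for each comparison, the real split included. They exchanged single arrays freely and took no account of arrays that share a sample-name number, whose correlation was 0.378. For such free exchange, chance was excluded for EE2 at 1, 2.5, 5 and 10 ppm at 7 d and for 10 ppm at 28 d, where 1 of 100 splits each reached the real 1515, 1657, 2770, 3783 and 3248 genes and the highest others had 615, 813, 1541, 2016 and 2189. It was excluded for PRED 5 and 25 ppm at 7 d and 25 ppm at 28 d, with 1 of 100 each, real counts of 68, 682 and 1123 and highest others of 19, 439 and 465. For PRED 1.25 ppm 17 of 100 splits reached 3 genes, so chance was not excluded. The highest other split, with 1590 genes, points to a structure of the samples, since it set feed control replicates 1, 2 and 6 with PRED 1.25 ppm replicate 4, from 4 chips. For PRED 2.5 ppm the real count was 0, which every split reaches (100 of 100, the highest having 154), so the splits decide nothing there.

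The splits also decide nothing for the other real counts of 0. For A4 35 of 35 splits reached 0 genes at each dose and duration, the highest others having 11, 4, 2, 9 and, at 28 d, 0. For trends, 1 of 100 splits reached the 3853 genes of EE2, with a highest other of 2336, 2 of 100 reached the 830 of PRED, the other having 1354, and 100 of 100 reached the 0 of A4, with a highest of 2. For differences between durations, 1 of 100 reached the 290 genes of EE2 (highest other 141), 1 of 100 the 161 of PRED (5) and 7 of 100 the 1 of A4 (2). For EE2 against PRED, 1 of 35 reached the 1118 genes at 2.5 ppm (highest other 324) and 1 of 35 the 2048 at 5 ppm (1282). For gavage against feed controls, 100 of 100 reached 0 at 7 d and at 28 d (highest 5 and 1). For genes changed the same way by both compounds, 1 of 100 reached 301 at 7 d (highest other 66) and 3 of 100 479 at 28 d (710). Under free exchange chance was thus excluded for EE2 and PRED trends and durations, matched comparisons and both overlaps, not for the A4 duration. Flat dose effects or unrelated compound effects could pass too. With the sample-name number as a random block durations had 110 genes for EE2 and 4 for PRED. The splits thus do not show how many of the 290 and 161 remain if arrays of a number are dependent.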

How the results depend on the processing

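Tests chosen after the results were seen were the background correction with nec, the runs without 2 control arrays, the list counts and shifts without 1 array and the run without arrays far from their group. Counts kept within 1.5 times in 283 of 346 other settings and in 274 of 324 runs without 1 array. Named genes kept their call and direction in 1792 of 1848 settings, were weaker in 55 and reversed in 1, and without 1 array were weaker in 144 of 1750. Lists kept their call in 566 of 651 settings, were weaker in 62, of which 41 with an estimated correlation, stronger in 21 and reversed in 2. Of 149 counts of called list members, 86 moved by over 1.5 times without some array, 72 of them counts of 3 or fewer. The cause was not tested for the values below, except that a fold minimum, fewer groups or fewer arrays leave fewer genes or less information by construction. Signal over background limits genes near the array medians of 105.7 to 106.4. No paired analysis was possible because the replicate numbers were given in accession order and pair nothing. The second value table and a mean over probes were not run, because its values were identical and each gene had 1 entry. No count moved with chip as a random block, a prior by mean level, a stricter filter, median centring, pseudocounts 1 and 50, or without far arrays.

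With chip as a fixed block, duration differences were 52 for PRED and 0 for A4. With the sample-name number as a random block, counts were 45, 425 and 685 for PRED 5 ppm, 25 ppm and 25 ppm at 28 d, 502 for the PRED trend, 110, 4 and 0 for EE2, PRED and A4 durations, and 181 and 279 for the overlaps. With only the groups compared, they were 641 and 1160 for EE2 1 and 5 ppm, 1 and 43 for PRED 1.25 and 5 ppm, 2529 for the EE2 trend, 347 and 0 for PRED and A4 durations, 443 and 231 for EE2 against PRED, and 4 for gavage against feed at 7 d. Without the filter, they were 6 for PRED 1.25 ppm and 180 and 83 for EE2 and PRED durations. With at least 1.5-fold, they were 486, 572, 862, 1191 and, at 28 d, 1061 for EE2, 35, 243 and, at 28 d, 413 for PRED, 174, 95 and 0 for EE2, PRED and A4 durations, 452 and 746 for EE2 against PRED, and 96 and 176 for the overlaps. With doses as scores the PRED trend had 547 genes, and without the control group the EE2 and PRED trends had 1651 and 262. With controls split, the overlaps were 123 and 249.5.

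With nec, counts were 773, 729, 1417, 1831 and, at 28 d, 1630 for EE2, 20 and, at 28 d, 600 for PRED, 1887 and 503 for the trends, 102, 49 and 0 for durations, 1004 for EE2 against PRED at 5 ppm, and 196 and 266 for the overlaps, and the Serpina9 difference turned to 0.0086 (adjusted p = 0.979). Without the 2 control arrays, PRED and A4 durations had 448 and 0 genes, gavage against feed 1 and 2, and with A4 at 7 d the interferon median turned to 0.064 and the MHC class II median to 0.10.

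Leaving out each array in turn gave 899 to 1737, 1193 to 1650, 1945 to 2987 and 2986 to 3784 genes for EE2 1, 2.5, 5 and 10 ppm, and 2684 to 3258 at 28 d. PRED gave 1 to 3, 0 to 1, 32 to 65 and 412 to 736 by dose, and 809 to 1315 at 28 d. A4 gave 0 to 1 at 2 mg/kg/day and 0 to 0 at each other dose and at 28 d. Trends gave 3179 to 4082 for EE2, 510 to 902 for PRED and 0 to 0 for A4. Durations gave 129 to 421 for EE2, without EE2 10 ppm replicates 3 and 1 at 7 d, 8 to 483 for PRED, without PRED 25 ppm replicates 4 and 1 at 7 d, and 0 to 1 for A4. EE2 against PRED gave 807 to 1118 and 1449 to 2431, gavage against feed 0 to 0 and 0 to 2, and the overlaps 182 to 320 and 359 to 569.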

Other observations

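The single-array values below were chosen after they were seen, and no test was run on them. With EE2 1 ppm, replicate 2 had low levels of genes that the other 3 arrays of its group had raised. Its Isyna1 intensity was 241, where the others lay between 4536 and 9763 and the 7-day feed controls between 132 and 571. Its Chst8 intensity was 110, against 254 to 1362 in the others and 105 to 122 in the controls, and Krt79 was not detected on it. On the same array Hsd3b5, at 184, lay below every control (6668 to 8029), and Cyp17a1, at 5948, lay above every control (193 to 491).

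With PRED 2.5 ppm, where no gene passed, the 4 arrays spread widely for genes that changed at the higher doses. Cyp17a1 intensities were 241, 459, 2525 and 3734 for replicates 1 to 4, against 193 to 491 in the 7-day feed controls. Car3 intensities were 10108, 7999, 1508 and 148, against 2503 to 7025.

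The A4 changes at 50 mg/kg/day were also set against the genes that EE2 and PRED had changed, across genes, which are not independent replicates. Of the EE2 10 ppm genes at 7 d, 30.2% had an A4 change of the same sign (r = -0.27, rho = -0.31), and of the PRED 25 ppm genes 45% (r = -0.02, rho = -0.17). At 28 d the shares were 55.5% for EE2 (r = 0.08, rho = 0.10) and 42.8% for PRED (r = -0.09, rho = -0.045). The A4 changes at 7 d and 28 d themselves correlated with r = -0.19 and rho = -0.15.

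In the feed controls, 36 genes were higher and 80 lower at 7 d than at 28 d. Limma called 0 genes between the gavage controls of 7 d and 28 d, where 555 had an unadjusted p under 0.05.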
